A study of Homo sapiens with 3 samples.

How the data were processed

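Total RNA from A2780 cells, a human ovarian carcinoma line, was hybridised to 3 two-colour Agilent expression arrays. Per the labels, cells were infected for 2 days with a control virus or with a lentivirus carrying CRISPR components against TET2, single clones were kept after about 8 weeks of puromycin selection, and cells grew in RPMI medium with 10% serum. Each array carried 1 TET2 knockout (KO) clone labelled with Cy5 and 1 control clone labelled with Cy3. KO clone 1.1 was paired with control clone 1, and KO clones 1.36 and 2.32 were each paired with control clone 2. The dyes were not swapped, so a dye effect and a KO effect lie on the same axis in every ratio. The 3 arrays shared 1 slide and 1 scan day per the file headers, so no slide or scan batch could be separated. Each KO clone was measured once. The replicates are therefore separate clones, and the spread between arrays holds the difference between clones as well as measurement error.

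The spot intensities were deposited as scanned. Per the file headers they came from Agilent Feature Extraction 10.7.3.1 on design 026652, whose annotation uses build hg19, and they are mean pixel intensities with a median local background on a linear scale. The same deposited files hold a log10 ratio of Cy5 over Cy3 that the scanner software had background-subtracted and dye-normalized, per the file headers. The authors also deposited a table of processed log2 ratios; limma is named in the submitters' processing notes, without a version or settings. That table was set against the scanner values. It matched log2 Cy5 over Cy3 with no background correction followed by loess best, with r of 0.996, 0.997 and 0.996 across spots on the 3 arrays and slopes of 0.996, 0.997 and 0.996. The column medians were -0.0043, -0.0023 and -0.0067 for clones 1.1, 1.36 and 2.32. Its scale and direction were thus found from the values, and its centring was that of loess within each array as far as this match shows.

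From the intensities, log2 ratios of KO over control were computed with limma 3.58.1 in R 4.3.3. Background was corrected with the normexp model and an offset of 50, and ratios were normalized by loess within arrays with the 1377 control spots at weight 0 and then left out. Spots that the scanner software had marked as non-uniform or as population outliers were set to missing (384, 487 and 514 of the 43118 gene spots). These spots were also kept out of the normexp fit. The plan fixed before the data were examined did not name this step, which was chosen after the fit on all spots had been run and had given 6 features past the threshold. On the array of clone 2.32, 5 spots had a local background above 500, up to 80052 in Cy3. No spot was saturated. Replicate spots of a probe were averaged. A feature was tested when its probe was well above background in at least 1 channel on at least 2 arrays, and the probe with the highest mean intensity stood for each gene. Of 34127 gene probes, 25422 were named through their RefSeq accession and 1545 through the design's symbol in a table of assembly GRCh38.p14, and 7160 kept their probe name. Coordinates are those of the probes in the design's hg19 annotation, which gives no exon or UTR, and no genome sequence was used here.

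The test was limma's moderated test of the mean log2 ratio against 0 over the 3 arrays, two-sided, with Benjamini-Hochberg adjustment over 19465 features and a threshold of 0.05. It leaves out the spread of the control. Changes of at least 1 on the log2 scale were also counted. Gene lists fixed in advance, 30 in all, were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Beside it stood camera with an estimated correlation, and fry, which tests whether a list's own genes move one way on balance. Adjusted p-values over a list's members alone are called adjusted over the list alone. Named genes were chosen by a rule fixed before the data were examined. The rule took TET2 and all TET and DNMT genes, the 10 largest increases and the 10 largest decreases past the threshold with the same direction on all 3 arrays, and up to 4 called members of each list by size, or the members with the smallest p where none was called. Some genes that the rule named are not reported here; they remain in the counts and list tests. Levels per channel came from loess followed by Aquantile normalization between arrays. A gene not well above background in the KO channel on any array has only a bound there. It was given as the control's mean over the KO mean of, per array, the higher of its own signal and the lowest signal among probes well above background; such bounds are open to dye bias and hold under the background model used.

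The test was tried on simulated data with the real spread for the comparison of KO with control, with 19465 features of which 200 were changed. It recovered 0% of the changes of 0.5 on the log2 scale, 66% at 1, 90% at 2 and 98% at 4, with 9 false calls among 136. No gene was called when none was changed. The spread between arrays leaves out a control that deviates alike on every array, and the ratios rested on nearly the same control profile. The simulation therefore cannot show false calls from such a control. In the data 1968 features passed, 491 of them with a change of at least 2-fold, so the recovery seen with 200 changed features need not carry over. In 30 simulated lists, the 1 changed list passed and 0 others did. Genes in these lists were simulated independently, so this cannot show false calls from correlated genes. In the data the estimated correlation was 0.665 for the ribosomal list. The number of arrays limits the precision, and their signal limits the range. Between 68.2% and 71.2% of gene spots were well above background in the KO channel and between 67.6% and 69.9% in the control channel. Slopes of observed on expected log ratios of the spiked-in control transcripts, from the file headers, were 0.857, 0.853 and 0.859, so that ratios of the scanner software were compressed by a similar amount on each array.

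Alternatives covered the background correction, the normalization, the authors' processed values, the filter on dim probes, the choice of probe, the variance model, the weight of the control clones, a fit of separate channels, and each array left out in turn. A normexp fit on all spots and raw signals for the differences between clones were added after the data had been examined.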

Results

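The series compared gene expression in 3 single-cell-derived TET2 KO clones of A2780 with that in 2 control clones prepared in parallel. TET2 is a dioxygenase that oxidises 5-methylcytosine, and the series title places it in the protection against abnormal DNA methylation under oxidative stress. The clones were measured on 3 arrays, each giving the ratio of 1 KO clone over 1 control clone. Of 43118 gene spots, between 29430 and 30720 were well above background in the KO channel and between 29147 and 30140 in the control channel. Values below are mean log2 ratios of KO over control ± SD over the 3 arrays (n = 3), and adjusted p-values are from limma unless another test is named.

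The first question was whether the targeted gene itself differed. TET2 mRNA did not pass the threshold. The brightest probe, in transcript NM_001127208 on chromosome 4 at 106193920 to 106193979, gave -0.27 for clone 1.1, -0.05 for clone 1.36 and -0.75 for clone 2.32, a mean of -0.36 ± 0.35 (adjusted p = 0.204). The other 3 TET2 probes had means between -0.14 and 0.03, and their clones disagreed in sign. The probe at 106200570 to 106200629 gave 0.51 for clone 1.36 and -0.32 for clone 2.32. Without loess the brightest probe's mean was 0.01, against a median of 0.22 over all features. A small insertion or deletion from CRISPR need not lower the mRNA, and the edited position is not given in the sources used here, so these probes do not check the KO labels. None of the other TET or DNMT genes passed, although without loess TET1 (0.59) and DNMT1 (0.62) did, and DNMT3L (1.90) did with the scanner software's ratios. TET1 stood at 0.23 ± 0.27, TET3 at 0.01 ± 0.05, and DNMT1, the maintenance methyltransferase, at 0.19 ± 0.21. DNMT3B stood at -0.13 ± 0.14, and DNMT3L, not well above background in the control, at 0.19 ± 0.12. The TET3 probe was well above background on 2 arrays only in each channel, and the other TET3 probe on 1. Its value near 0 therefore does not show that TET3 was unchanged. The brightest DNMT3A probe gave 1.19 in clone 1.36 but -0.20 and 0.35 in clones 1.1 and 2.32. Another DNMT3A probe gave 1.05 in clone 1.36, but the remaining probe gave -0.42 there and 0.35 in clone 1.1.

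Large decreases made up most of the strong differences between KO and control. AMIGO2, an adhesion molecule, had the lowest mean, -5.45 ± 0.70 (adjusted p = 0.00386). IL23A, a subunit of interleukin 23, stood at -4.65 ± 0.11, the kinase gene NRK at -4.62 ± 0.11, the cytokine gene TNF at -4.41 ± 0.33 and ADM, which encodes the peptide adrenomedullin, at -4.20 ± 0.16. ANK3, an ankyrin that anchors membrane proteins, fell by 3.71 (SD 0.14), and its other probes gave -2.33 and -1.39. The other 4 of the 10 largest decreases were PRAMEF4 (-4.50 ± 0.50), PRAMEF15 (-4.48 ± 0.42), PRAMEF5 (-4.21 ± 0.44) and PRAMEF11 (-3.68 ± 0.25), members of a family of near-identical copies whose probes may cross-hybridise, so that the single members are uncertain. The sizes of decreases that end near background depended on the background setting and the probes used: over the alternatives the mean ran from -7.46 to -4.34 for AMIGO2 and from -6.97 to -2.78 for NRK, each with a KO channel well above background on 2 arrays, as also for TFPI2, ITGAX, CD52 and DCN, named further on. A second NRK probe gave -0.93 and a second PRAMEF15 probe -1.30. The AMIGO2 probe lies on chromosome 12 at 47470931 to 47470990, and that of TNF on chromosome 6 at 31545837 to 31545896.

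Increases were smaller. TSPAN8, a tetraspanin, led with 2.51 ± 0.15 (adjusted p = 0.0017), followed by CDKN2A, the locus of the cell cycle inhibitor p16, with 2.41 ± 0.39 (adjusted p = 0.00714) and 2.69 on its second probe. The CDKN2A probe lies on chromosome 9 at 21968039 to 21968098. The growth factor gene FGF18 stood at 2.16 ± 0.22, the ephrin receptor EPHA7 at 1.81 ± 0.06, LGR5, a receptor for R-spondins, at 1.87 ± 0.40, and FGFBP3 at 1.79 ± 0.25. GSG1 (2.17 ± 1.02) and LARP6 (1.85 ± 0.52), also among the 10 largest increases, had more spread between clones, and the other probes of GSG1 gave 0.31 and 2.20.

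**Figure D1:**
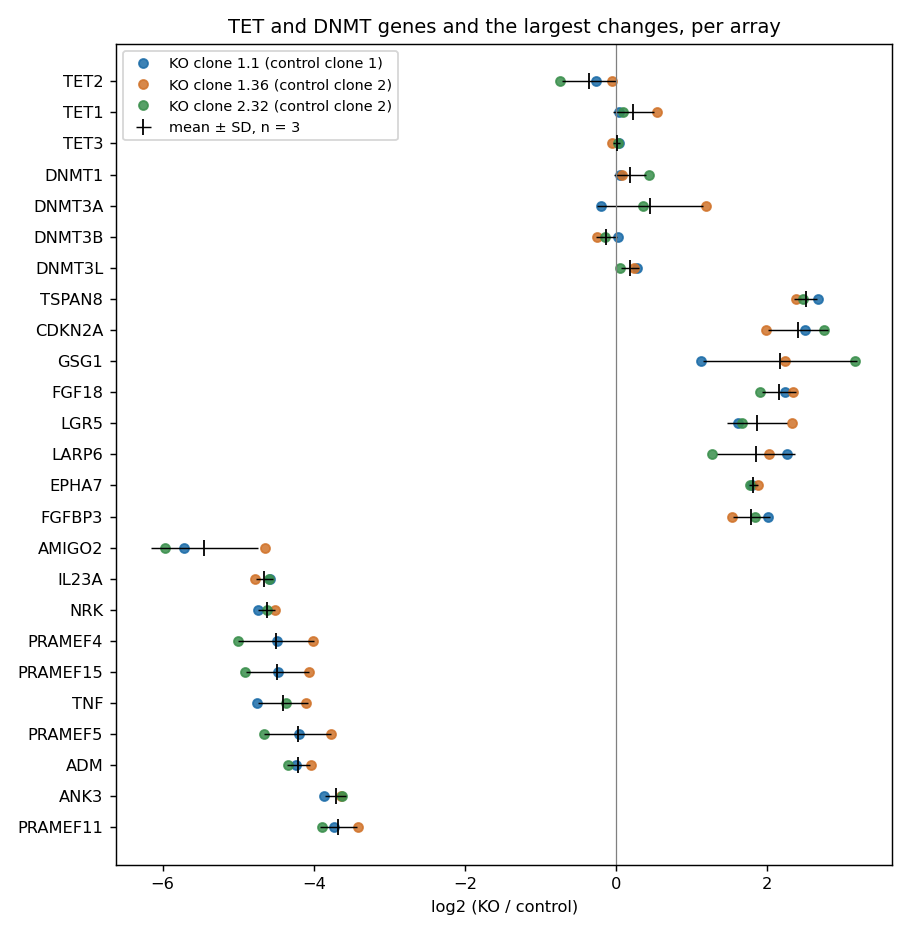
Log2 ratio of KO over control (horizontal axis) for TET and DNMT genes and the reported genes among the 10 largest increases and decreases; coloured points are the 3 arrays, ticks and bars the mean ± SD (n = 3). TET2 lies between -0.75 and -0.05, while AMIGO2 lies below -4 in every clone.

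In all, 1968 of 19465 features passed the threshold, 727 higher and 1241 lower in the KO clones, each in the same direction on all 3 arrays. A change of at least 2-fold was seen for 491 of them, 82 higher and 409 lower, and 43 fell at least 8-fold while 0 rose that far. In 141 of the called decreases the KO channel was not well above background on any array. Without loess, median centring moved the median of all features to 0.22 and gave 7042 higher and 1539 lower calls, and the scanner software's own ratios gave 1165 and 1120, so the balance of small increases and decreases depends on the normalization. The count rests on the background model too. The plan fixed before the data were examined did not leave outlier-marked spots out of that model, and with the model fitted on all spots 6 features passed, 2 higher and 4 lower, with 2949 at an unadjusted p under 0.05. Leaving those spots out was chosen after that count had been seen. Without any background correction 2106 features passed, and 2064 passed with the values processed by the authors. The count also changed with the arrays used: it was 102 without clone 2.32, 430 without clone 1.1 and 2956 without clone 1.36, and 948 with the control clones weighted equally. Fewer arrays lower the power, so a fall in the count need not come from the clone left out.

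Genes were next grouped by the 30 lists fixed in advance. With the preset correlation, 12 lists were lower and 2 higher in KO than other genes. With an estimated correlation 0 passed, and the smallest adjusted p was 0.344. In fry, which does not compare a list with other genes, 10 passed; they include reactive oxygen detoxification (0.0206) and leukocyte markers (0.0361), which camera did not call, and leave out the interferon, ribosomal, cell cycle, Polycomb, mitochondrial and heat shock lists.

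The NF-kB and inflammatory genes had the lowest mean of any list, -1.73 ± 0.06 over the clones. Of 17 measured members 11 fell and 0 rose (15 and 0 adjusted over the list alone; camera adjusted p = 8.12e-11, and adjusted p = 0.344 with an estimated correlation). Besides TNF they held BIRC3, an inhibitor of apoptosis, at -3.67 ± 0.45, and the acute-phase genes SAA1 (-3.31 ± 0.06) and SAA2 (-3.09 ± 0.06), which are near-identical copies. Of 20 immediate early genes, which respond within minutes to growth signals, 10 fell and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p = 8.54e-07, and adjusted p = 0.344 with an estimated correlation). EGR2 stood at -1.58 ± 0.04, ATF3 at -1.56 ± 0.37, DUSP6 at -1.38 ± 0.32 and IER3 at -2.10 ± 0.96. The other 3 ATF3 probes ranged from -1.47 to -0.14. Markers of stromal cells moved the same way: 6 of 13 fell and 0 rose, with a list mean of -1.20 ± 0.14 (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 5.84e-05, and adjusted p = 0.344 with an estimated correlation).

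Mesenchymal genes, which share 12 genes with the stromal markers, fell in 14 of 33 cases and rose in 1 (23 and 2 adjusted over the list alone; camera adjusted p = 2.06e-08, and adjusted p = 0.344 with an estimated correlation). COL6A3, a collagen VI chain, was at least 9.38-fold lower under the background model used, with no KO channel well above background (adjusted p = 0.00156). Its mean ran from -6.55 to -1.83 over the alternatives, and its second probe gave -0.41. CCN2, a matricellular protein, stood at -3.08 ± 0.65, the transcription factor SNAI2 at -2.99 ± 0.16 and the collagen gene COL1A1 at -2.79 ± 0.33. Among the stromal markers COL1A2, with a KO channel well above background on 1 array only, was lower with a mean from -3.78 to -1.10 over the alternatives, and DCN, which encodes decorin, stood at -1.46 ± 0.42, though the second DCN probe gave -0.20. The epithelial list did not pass (camera adjusted p = 0.35), with 1 higher and 3 lower of 22 (2 and 4 adjusted over the list alone), but did without clone 1.36 (0.0298); the keratins KRT19 (-1.82 ± 0.22) and KRT18 (-1.57 ± 0.52) and the tight junction gene CLDN4 (-1.10 ± 0.20) fell, and OCLN, another tight junction gene, rose by 0.91 ± 0.31. Of the other cell type markers, 3 of 17 leukocyte genes fell, ITGAX (-2.04 ± 0.06), CD52 (-1.53 ± 0.33) and ITGAM (-0.43 ± 0.05), in a list with a mean of -0.27 and a median of 0.06 (camera adjusted p = 0.724). Of 6 endothelial genes 0 passed (camera adjusted p = 0.953).

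Stress-related groups followed. Of 12 measured metallothioneins and zinc genes, whose products bind or carry metals, 7 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.00164, and adjusted p = 0.346 with an estimated correlation). MT2A stood at -3.57 ± 0.52, MT1L at -2.25 ± 0.18 and MT1E at -2.23 ± 0.13, from genes similar enough to share probes. Hypoxia and HIF targets fell in 6 of 30 cases and rose in 2 (12 and 2 adjusted over the list alone; camera adjusted p = 0.000317, and adjusted p = 0.346 with an estimated correlation), led by ADM, ANGPTL4 (-2.96 ± 0.25), which inhibits lipoprotein lipase, and P4HA2 (-1.71 ± 0.33), a collagen prolyl hydroxylase. Interferon-stimulated genes, with list means of -0.55, -0.21 and -0.54 in clones 1.1, 1.36 and 2.32, fell in 8 of 37 cases and rose in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 5.84e-05, and adjusted p = 0.476 with an estimated correlation), led by ISG20 (-2.85 ± 0.26), IFIT2 (-1.09 ± 0.47) and OAS2 (-0.83 ± 0.27). The oxidative stress lists did not pass in camera. In fry, reactive oxygen detoxification passed (adjusted p = 0.0206) and NRF2 targets did not (adjusted p = 0.0516). NRF2 targets had 1 higher and 5 lower of 32 (2 and 6 adjusted over the list alone; camera adjusted p = 0.125), including SQSTM1, an autophagy receptor (-1.19 ± 0.21), and TXNRD1, thioredoxin reductase (-0.65 ± 0.24). Reactive oxygen detoxification genes had 2 higher and 6 lower of 34 (4 and 8 adjusted over the list alone; camera adjusted p = 0.0799, with a range of 0.0315 to 0.837 over the alternatives), including MGST1, a microsomal glutathione transferase (-2.01 ± 0.43), PRDX6, a peroxiredoxin (-0.74 ± 0.23), and MSRB2 (0.81 ± 0.23). Without loess the means of both lists were above 0, at 0.20 and 0.21, against a median of 0.22 over all features.

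Among chromatin lists, Polycomb and Trithorax complexes were higher as a group, with 4 of 38 higher and 2 lower (12 and 4 adjusted over the list alone; camera adjusted p = 0.0061, and adjusted p = 0.699 with an estimated correlation). KMT2A, a histone H3K4 methyltransferase, rose by 0.76 ± 0.05, with its other probes between 0.35 and 0.83, and BMI1, a Polycomb protein, rose by 0.71 ± 0.24. Acetylation writers and erasers did not pass as a list (camera adjusted p = 0.207), with 4 higher and 1 lower of 27 (7 and 2 adjusted over the list alone). The acetyltransferase genes KAT6B (0.66 ± 0.06) and CREBBP (0.63 ± 0.09) rose, and HDAC2, a deacetylase, fell by 1.17 (SD 0.20), although second probes of KAT6B (-0.02) and HDAC2 (-0.07) did not follow. In the DNA methylation and demethylation machinery 1 of 30 genes passed, also over the list alone, GADD45A at -1.80 ± 0.23, a stress-inducible gene tied to DNA repair and demethylation (camera adjusted p = 0.799). HOX genes, which pattern the body axis, had 4 of 18 lower and 1 higher (6 and 3 adjusted over the list alone; camera adjusted p = 0.0084, and adjusted p = 0.346 with an estimated correlation), with HOXB6 at -2.83 ± 0.75 and HOXB9 at -2.42 ± 0.23. Tumour suppressors often silenced by promoter methylation did not pass (camera adjusted p = 0.783), with 2 higher and 6 lower of 45 (4 and 11 adjusted over the list alone). Besides CDKN2A, PCDH10 rose by 1.34 ± 0.24, though its second probe gave -0.42, while TFPI2 (-2.08 ± 0.43) and the Wnt inhibitor WIF1 (-1.35 ± 0.41) fell. Imprinted genes (camera adjusted p = 0.121) had 2 higher and 5 lower of 22 (2 and 7 adjusted over the list alone), with DLK1 at -2.70 ± 0.78, PHLDA2 at -2.62 ± 0.45 and IGF2 at -1.13 ± 0.35; the second DLK1 probe gave -0.59. Developmental regulators marked by Polycomb in stem cells (camera adjusted p = 0.911) had 2 higher and 3 lower of 50, the same over the list alone, with FOXL2, an ovarian transcription factor, lower. Its KO channel was well above background on 1 array only, its mean ran from -4.77 to -1.68 over the alternatives, and its second probe gave -1.03. Cancer-testis and germline genes (camera adjusted p = 0.783) had 1 of 12 lower, PRAME at -0.79 ± 0.28. The mean and median of these last 2 lists, of the endothelial list and of the tumour suppressors differed in sign.

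In the Wnt list 7 of 32 rose and 4 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.783). The receptors LGR5, LGR4 (1.34 ± 0.18) and FZD1 (1.20 ± 0.10) rose and the ligand WNT6 fell by 2.25 (SD 0.35). The TGF-beta and BMP list held 4 higher and 4 lower of 32 (5 and 4 adjusted over the list alone; camera adjusted p = 0.68), with TGFB3 at -1.32 ± 0.36, the inhibitor SMAD6 at 1.16 ± 0.34, and INHBA, an activin subunit, at least 2.34-fold lower under the background model used, with a mean from -3.49 to -0.84 over the alternatives. Ribosomal proteins had a mean of 0.24 ± 0.21 (camera adjusted p = 2.11e-05, and adjusted p = 0.715 with an estimated correlation), with 1 of 42 called, RPS2 at 0.71 ± 0.27 with other probes at 0.13 and 0.34, and 0 over the list alone. Small shifts downward in 4 lists passed with the preset correlation and turned above 0 without loess: cell cycle (-0.22 ± 0.24, camera adjusted p = 0.00164), p53 targets (-0.32 ± 0.05, 0.00971), the mitochondrial respiratory chain (-0.12 ± 0.10, 0.0178) and heat shock (-0.32 ± 0.13, 0.0322). Their adjusted p-values with an estimated correlation were 0.803, 0.346, 0.715 and 0.715. They held 2 of 46, 4 of 27, 0 of 39 and 2 of 17 lower members, respectively (2, 7, 0 and 2 adjusted over the list alone), and TIGAR (0.62 ± 0.15) was the 1 p53 target that rose. Without loess the median of all features was 0.22. The cell cycle (0.21), p53 (0.082) and heat shock (0.18) list means lay below that median, and the respiratory chain mean (0.42) lay above it. CDK1 stood at -1.12 ± 0.30, CDC20 at -0.77 ± 0.09, PLK3 at -0.82 ± 0.26 and HSPB1 at -1.10 ± 0.40. DNA repair (camera adjusted p = 0.135; 1 higher and 4 lower of 39, the same over the list alone, with MLH3 at -1.12 ± 0.03), the unfolded protein and integrated stress response (0.783; 2 and 1 of 30, the same over the list alone) and cholesterol synthesis (0.783, but 0.00052 without clone 1.36; 1 and 0 of 23, the same over the list alone) did not pass.

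**Figure D2:**
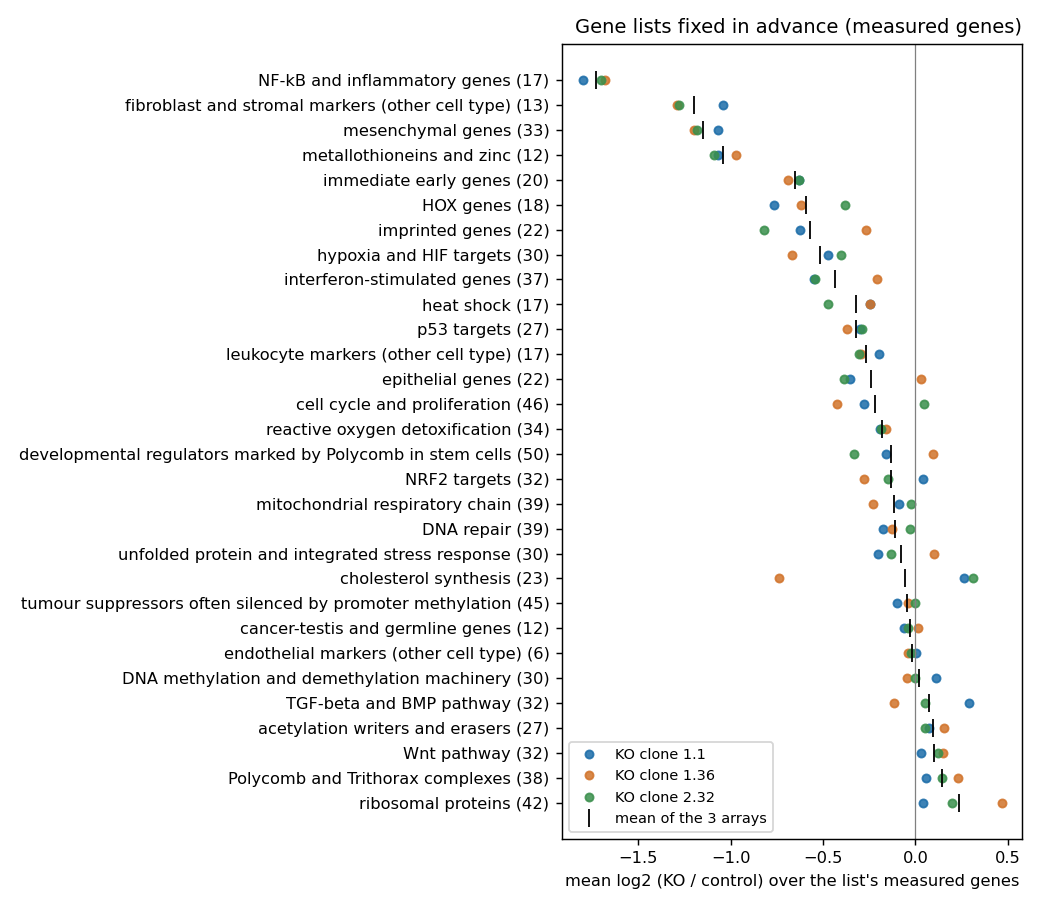
Mean log2 ratio of KO over control (horizontal axis) over the measured genes of each of 30 lists, with the number of measured genes in brackets; coloured points are the 3 arrays and ticks their mean. NF-kB and inflammatory genes lie near -1.73 in every clone, while cholesterol synthesis lies at -0.74 in clone 1.36 and near 0.3 in the others.

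The agreement between KO clones was then described across the 19465 features, which are not independent replicates. Clones 1.1 and 2.32, which had different control clones, were the most alike, with r = 0.80 and 570 features changed at least 2-fold the same way. Clones 1.36 and 2.32, which shared control clone 2, had r = 0.62 and 435 such features, and clones 1.1 and 1.36 had r = 0.51 and 416. At least 2-fold decreases in all 3 clones were seen for 309 features and increases for 43. Unchanged clones simulated against 1 shared control gave r = 0.50 whatever the spread, a value fixed by giving clones and control equal spread. Their covariance was 0.006 with the spread seen between the control clones and 0.0986 with that between the KO clones, against observed covariances of 0.198, 0.157 and 0.135. The simulated control varied at each gene only as much as the clones did. The simulation therefore cannot show what a control that alone deviates would add, and nothing is concluded from it. The controls are too few to part what a shared control adds from what the KO clones share.

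The last comparison set clones against each other within a dye. KO clones differed widely. The number of features at least 2-fold apart was 865 between clones 1.1 and 1.36, 645 between clones 1.36 and 2.32 and 270 between clones 1.1 and 2.32. Control clones 1 and 2 differed at least 2-fold in 1 feature, PDZD4, at 1.04 and 1.08 against the arrays of control clone 2, and the 2 hybridizations of control clone 2 in 0. The SD of the log2 difference was 0.108 and 0.110 between the control clones, 0.0821 between the hybridizations of control clone 2, and 0.33 to 0.519 between KO clones. The 3 ratios therefore rested on nearly the same control profile, and no clone was hybridised with both dyes.

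**Figure D3:**
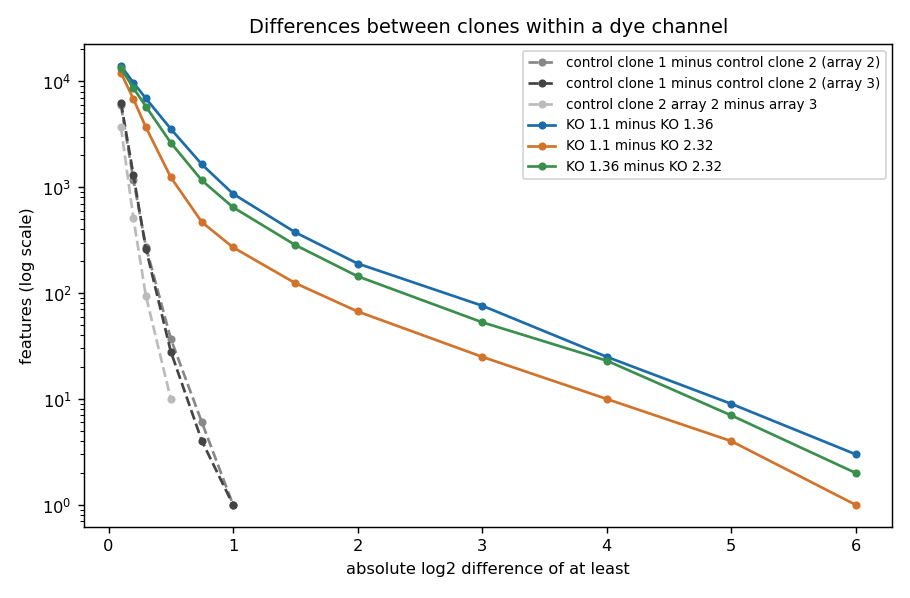
Number of features (vertical log axis) whose log2 level differed by at least the value on the horizontal axis, between pairs of clones in the same dye. Solid lines are pairs of KO clones, dashed lines pairs of control hybridizations. At an absolute difference of 1 the control pairs lie at 1 feature or fewer and the KO pairs between 270 and 865.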

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

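The normexp fit on all spots and the raw signals were chosen after the data had been examined. No further pairing was possible, because the labels give a single group and the tested ratios already pair each KO clone with the control on its array. The control clone as a random block was not run, since limma gave no correlation with 3 arrays. The counts of 1968 features past the threshold, 727 higher, 1241 lower and 491 at least 2-fold stayed within 1.5 times with no background correction, scaling between arrays, the authors' processed values, no filter or a stricter one, the mean of all probes, each probe by itself, and a variance trend. The main setting departs from the fixed plan: fitted on all spots, the normexp model gave 6 features (2 higher, 4 lower, 6 at least 2-fold). The total became 8581 with median centring (7042 higher, 918 at least 2-fold), 948 with the control clones weighted equally (250 higher, 698 lower) and 4829 with separate channels (2205 and 2624). The scanner software's ratios gave 1165 higher and 1250 at least 2-fold, and an offset of 0 gave 936 at least 2-fold. Leaving out 1 clone gave 102 (clone 2.32), 430 (clone 1.1) and 2956 (clone 1.36) features, with 5 to 1131 higher, 97 to 1825 lower and 102 to 714 at least 2-fold; fewer arrays lower the power, yet without clone 1.36 the count rose. Of the 14 lists that passed, 0 did with an estimated correlation. With the preset one the cell cycle, heat shock and respiratory chain lists lost the call without clone 1.36, heat shock without clone 2.32, the stromal list with the stricter filter and the HOX list with no filter. Lists that had not passed gained a call, also with the preset correlation alone: reactive oxygen detoxification under 5 of 13 settings (lowest adjusted p 0.0315), acetylation writers and erasers (0.0307) and leukocyte markers (0.0307) with median centring, epithelial (0.0298) and imprinted genes (0.0224) without clone 1.36, and DNA repair (0.0239) without clone 2.32. Cholesterol synthesis passed as higher without clone 1.36 (0.00052), and the respiratory chain passed as higher with median centring. Under the normexp fit on all spots r was 0.572 for clones 1.1 and 2.32 and 0.471 for clones 1.36 and 2.32; with the scanner software's ratios, median centring and both filters each r moved by less than 0.146, the SD of the 3 values. The cause was not tested.

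Of the 103 named genes that passed, 102 lost the call with the normexp fit on all spots, 80 without clone 2.32, 48 without clone 1.1, 2 without clone 1.36, 23 with the control clones weighted equally, 13 with the scanner software's ratios and 12 with median centring, where HLA-B (0.019) and PCGF1 (0.010) also turned. Other means that turned there were TET2 (0.0099), TET3 (-0.17), DNMT3B (0.26), DNMT3L (-0.043), SDHC (0.12), NRF2 targets (0.20), reactive oxygen detoxification (0.21), p53 targets (0.082), developmental regulators (0.078), tumour suppressors (0.20), the cell cycle (0.21), the unfolded protein response (0.42), heat shock (0.18), cholesterol synthesis (0.39), DNA repair (0.26) and the respiratory chain (0.42), against a median of 0.22 over all features. The TET3 mean log2 ratio, near 0, was -0.0066 with the authors' values, -0.0024 with the normexp fit on all spots, and -0.012 to 0.033 when 1 clone was left out. The TGF-beta list stood at -0.031 with an offset of 0 and -0.099 with the scanner software's ratios, which gave 0.16 for the cancer-testis list and -0.044 for the Wnt list. The endothelial list stood at 0.025 without the filter and the tumour suppressors at 0.0049 with the stricter one. With 1 clone left out the TGF-beta list ran from -0.032 to 0.17, the methylation machinery from -0.022 to 0.055 (both lowest without clone 1.1), and cholesterol synthesis from -0.24 to 0.29, the highest without clone 1.36. The cause was not tested. Signal over background limits the low end: in 141 called decreases the KO level is known only as a bound.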

Other observations

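The test of the spread between the control clones and the comparison of raw signals were chosen after the result had been seen; the other tests were set before their results, on patterns already noticed. Single genes with large differences between KO clones, chosen after their values were seen, are given as log2 ratios over control for clones 1.1, 1.36 and 2.32. VIM, which encodes the mesenchymal filament protein vimentin, stood at -5.70, -5.55 and -0.24. The transcription factor genes KLF5 and MITF stood at -0.29, 5.91 and -0.20, and at 1.70, -3.15 and 2.14. The deiodinase gene DIO3 stood at 3.93, -2.17 and -2.07. Cholesterol synthesis genes had means of 0.265, -0.74 and 0.309. With all clones that list did not pass (camera adjusted p = 0.783 with the preset correlation and 0.965 with an estimated one, which was 0.665).

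At least 2-fold changes shared by the KO clones have several candidate sources. They include probe-specific dye bias, differences between clones whatever their TET2, and the loss of TET2. Dye bias tied to single probes is argued against as the whole cause in the 114 called genes with another probe. Of 139 other probes, 97.1% had the sign of the called probe. Their medians were smaller, -0.93 against -1.68 in genes that fell and 0.72 against 1.33 in genes that rose. Probe sequences were not compared, so probes of a gene that overlap could share such a bias. To weigh clone differences, each of 4 profiles, the 3 KO clones and the control, was put in the place of the control against the others. The control gave 492 features past the threshold and at least 2-fold, and was the only 1 of the 4 places with as many. The highest other, KO clone 1.36, gave 393, and 4 places cannot give a share under 0.05. By all features past the threshold clone 1.36 gave 2326 and the control 1916, while clone 1.1 gave 27 and clone 2.32 gave 2. The control was the sole profile in Cy3 and a mean of hybridizations. TET2 loss and a difference between clones whatever their TET2 cannot be told apart, because the control clones amount to nearly 1 profile. The KO clones had received the lentivirus with CRISPR components and the control clones a control virus. An effect of the virus, or of a state that the control clones shared, therefore cannot be separated from TET2 loss either.

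Control clones 1 and 2 differed far less from each other than KO clones did, with an SD of the log2 difference of 0.108 and 0.110 against 0.33 to 0.519. In raw signals 1 feature was at least 2-fold apart between the control clones and 293 to 929 between KO clones. A compressed Cy3 channel is argued against, since the SD across features of the background-subtracted log2 level in Cy3 was 0.854 of that in Cy5. One control culture or RNA under both names stays open, as does a pair of clones that hardly diverged. The spread between the control clones was 1.33 times that between hybridizations of control clone 2, and control clone 1 was on 1 array only, so that these cannot be told apart.

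Stromal and inflammatory genes were lower in the KO clones together, and stromal cells mixed into the control cultures are a candidate source, although the labels say that single clones were kept. Of 6 abundant stromal transcripts, 0 failed to be well above background in the control channel, which leaves this open. The condition is weak, since 67.6% to 69.9% of gene spots met it in the control channel of an array. Mean control levels of the 6 transcripts on the normalized log2 scale were 9.81 for COL1A1, 7.63 for COL1A2, 7.76 for COL3A1, 7.90 for DCN, 6.30 for LUM and 11.9 for POSTN. Among tested features these levels lay at percentiles 70.3, 38.5, 40.7, 43, 7.11 and 90.2, in that order. POSTN was higher in KO clone 1.1 than in the control, by 1.35, and lower in clones 1.36 and 2.32 (-5.24 and -3.76), so cells in the control are not its sole source. The 13 measured stromal markers differed between control clones 1 and 2 by -0.121 to 0.104 on the log2 scale, so separately grown cultures would have needed nearly the same share of such cells. Of the 14 genes of this list 12 are also in the mesenchymal list, and the cancer cells themselves may express them.

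The PRAMEF family was lower in the KO clones. All 12 measured members passed the threshold, with a mean of -2.61, and all 12 did so with the scanner software's ratios and with median centring. Without clone 2.32 there were 7 that passed, with a mean of -2.50, and without clone 1.1 there were 10, with a mean of -2.63. With the normexp fit on all spots 0 passed, with a mean of -1.97. RFPL4A (-3.54 ± 0.38) and KHDC1 (-3.13 ± 0.14) fell as well, and RFPL4B was at least 8.46-fold lower under the background model used, with no KO channel well above background; these were chosen after their values were seen. Many of these genes are known from cleavage-stage embryos, where the transcription factor DUX4 drives them. The hypothesis was that a cleavage-stage gene programme was active in the control clones and lower in the KO clones. It was tested on 20 other such genes listed before their values were looked up, of which 16 were on the array. Of these, 68.8% were well above background in the control on at least 2 arrays and lower in every KO clone, against 26.3% of all tested features. All 16 met the first condition, including those not lower in every KO clone, so that condition shows little by itself. Past the threshold 8 of 16 were lower and 0 higher, against 6.38% lower among all features (Fisher's exact test, two-sided, p = 2.17e-06, which treats genes as independent; camera p = 7.55e-07, and 0.0547 with an estimated correlation). That number was 3 without clone 2.32, 6 without clone 1.1 and 0 with the normexp fit on all spots. The means there were -0.989, -1.14 and -0.764, against -1.10. ZSCAN4 stood at -2.70, TRIM43 at -3.18, TRIM48 at -2.35, MBD3L2 at -2.63 and SLC34A2 at -1.48, and CCNA1, with no KO channel well above background, was at least 1.87-fold lower under the background model used. TRIM49 and TRIM51 fell far in clone 2.32 alone (-3.22 and -2.96), and DUXA (0.0030), ARGFX (0.13), HNRNPCL1 (-0.057), FAM151A (-0.043) and RFPL2 (-0.20) did not follow. The values are consistent with such a programme in the control. They do not show whether TET2 is involved, since the control clones amount to nearly 1 profile, and several of these genes have near-identical copies that share probes.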
